A study of Mus musculus with 8 samples.

How the data were processed

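RNA from the colonic mucosa of C57Bl/6J wild-type (WT) mice and of C57Bl/6J mice labelled Nod2-/- was hybridised to 16 Agilent Whole Mouse Genome 4x44K arrays in 2 colours. The labels place all mice in an experimental model that they call CAC initiation. They describe colonic biopsies of untreated mice, of mice given an antibiotic cocktail and of mice given metronidazole, and do not say how many mice stand behind an extract. The 16 arrays make 8 samples, each a dye-swapped pair of arrays that compares the same pair of RNA extracts. The 8 samples cover 7 distinct comparisons of 8 RNA extracts, 4 per genotype, and 6 of the comparisons have no replicate. The arrays lay on 4 slides with 4 arrays each, were scanned within 1 day, and each dye-swapped pair lay on 1 slide.

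The scanner tables give the mean pixel intensity of each spot and the median intensity of its local background in the Cy5 and Cy3 channels, read with Mapix 2.6.1 per the file headers. The percent of saturated pixels per spot also comes from these tables, per the file headers. Labelling used the Quick Amp kit with 1 µg of RNA that had been treated with DNase on an RNeasy column, per the labels' protocols. The deposited values of each probe and sample were treated as log2 ratios of both channels. The submitters name limma for them, without a version, and state neither scale nor direction. Against the ratios computed here their columns had a Pearson r across probes of 0.928 to 0.963 and a slope of 1.19 to 1.27 (1.08 to 1.13 on 14389 bright probes, with a mean log2 intensity of at least 10). Between 88.4% and 93.7% of probes had the same sign, and the column medians ran from -0.0337 to 0.0387, so that these values were read as log2 in the same direction. Which extract carried which dye was taken from the deposited names together with the labels. Sums of ratios around closed loops of comparisons settle the direction of each ratio relative to the others, not the direction of all at once.

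Each array had 45220 spots, of which 43379 were gene probes, 153 negative controls, 1486 positive controls and 202 marked to be ignored. Background was subtracted with limma's normexp method (offset 50), dyes were normalised by loess within each array with control spots at weight 0, and ratios were not scaled between arrays. Spots of the same probe were averaged. A probe was kept when its signal in every channel of at least 1 extract lay 2.6 standard deviations above the negative controls, since the tables carry no processed signal or detection call; 22267 of 41174 probes were kept. Of the 41174 probes, 32664 had 1 gene symbol, 45 had several and 8465 had none, and 32524 were matched through their Entrez number to the gene table of mouse assembly GRCm38.p6, which changed 0 symbols. Each gene was represented by the kept probe with the highest mean intensity, which left 13385 genes, 4821 of them with over 1 kept probe. The array names no genome build, so positions served only to find neighbours of Nod2. Between 51.4% and 59.4% of spots were detected in Cy5 and between 47.4% and 54.1% in Cy3, and between 1.27% and 2.08% of Cy5 spots had at least 50% of their pixels saturated (Cy3, 0.00461% to 0.334%), which compresses ratios of the brightest genes. The number of arrays and extracts limits the precision.

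The dye-swapped arrays were averaged into 1 log2 ratio per sample, and the 8 ratios were turned by least squares into 1 log2 level per RNA extract. Linear models and moderated statistics came from limma 3.58.1 in R 4.3.3, with the package data.table (version 1.17.8). A gene passed the test at a Benjamini-Hochberg adjusted p under 0.05. The effects averaged over the other factor (Nod2 deficiency, antibiotics, metronidazole) came from an additive model. Direct comparisons and the genotype by treatment interactions came from a model with 1 term for each genotype and treatment. The models, the tests, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, apart from the changes given here.

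The replicate untreated genotype pairs differed by a standard deviation of 0.0818 per ratio across genes, which is no more than the 0.0947 and 0.0953 per ratio by which the closed loops with antibiotics and metronidazole missed 0. Their spread is therefore that of hybridisation, and whether they come from different mice cannot be seen in the data. After this was seen, the averaged effects were fitted with the untreated replicates merged into 1 pair, so that 6 extracts entered, with 2 residual degrees of freedom and 1.99 from the prior. The residual then holds the difference between the genotypes' responses. The planned model, with the untreated replicates as separate extracts, called 0 genes for Nod2 deficiency (1084 at an unadjusted p under 0.05), 26 for antibiotics and 2 for metronidazole. The direct comparisons and interactions kept the planned model, with 1 residual degree of freedom and 2.99 from the prior. Their p-values rest on the difference between the untreated pairs and so compare these extracts, not the conditions.

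Gene lists numbered 29, of which 27 had at least 5 measured genes and were tested. The immune lists cover NOD and Toll-like receptor signalling, antimicrobial proteins, inflammatory cytokines and chemokines, interferon response, MHC class II, B cells, T cells, and neutrophils and macrophages. The epithelial and metabolic lists cover goblet cells, absorptive colonocytes, enteroendocrine and tuft cells, stem cells and Wnt targets, proliferation, xenobiotic and bile acid handling, fatty acid oxidation and sterol synthesis. The others cover extracellular matrix, smooth muscle, enteric neurons and glia, adipocytes, squamous epithelium, pancreas and small intestine, colon position, circadian clock, immediate early genes, endoplasmic reticulum stress, and hypoxia. The erythrocyte and plasma list (3 genes measured) and the sex-linked list (1 gene) were not tested. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 27 lists and 4 contrasts, and again with an estimated correlation and with fry. Gene counts within a list were also adjusted over the list alone. In comparisons without replicates a list's median was placed among those of 10000 random lists of the same size matched on intensity. Random lists lack the correlation among the genes of a list. Wrong matches of old symbols for 2 list members (Il25 and Chat) were corrected after values had been seen, which moved the lists past the test for antibiotics to 21.

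Named genes follow this rule. Nod2 comes first. For the averaged effects and for Nod2 deficiency in untreated mice, the 10 genes with the largest change in each direction among those past the test are named, and free places are filled in order of p among genes with the same sign in every contributing pair and both dye orientations, called not past the test. For the other direct comparisons and the interactions 5 genes in each direction are named. Only genes with ordinary symbols are named, and from each list the 4 members with the largest absolute change and any past the test. The parts of the rule on comparisons named 102 genes, list members apart; 29 had another kept probe, which had the opposite sign for 0 of them. In 49 of the 150 named comparisons between groups the gene was detected in only some channels of a group and in 0 in none of them, so no value is a bound. Values of genes detected in few channels rest on signals near background, and the lowest shares are given with them. Genes of the cornified epidermis were counted as dim when detected in at most 50% of untreated WT channels.

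The steps were tested on simulated data with 67, 67 and 66 genes changed by 0.5, 1 and 2 on the log2 scale among 13385. For antibiotics averaged over genotypes 1.49%, 58.2% and 90.9% of the changed genes were recovered, with 7 false calls, and for Nod2 deficiency averaged over treatments 14.9%, 79.1% and 97.0%, with 5 false calls. For Nod2 deficiency in untreated mice and under antibiotics, with hybridisation noise alone, 100% were recovered at each size, with 14 and 3 false calls. Metronidazole and the interactions were not simulated. In the simulation genes varied independently and shared 1 level of hybridisation noise, which need not hold in the data. In the data 0 of the 125 genes at least 2-fold higher and the 190 at least 2-fold lower with antibiotics passed. The rates are therefore not the power of the averaged tests here, and 0 calls do not show that large changes were absent.

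Alternatives tried for preparing the data were no background correction, median centring in place of loess, no filter and a stricter filter on dim probes (16927 probes), and the mean of all kept probes of a gene. Alternatives for the model were an intensity trend with robust moderation, a single-channel model, all 16 arrays as observations with 1 dye term or 1 per slide, only the ratios that measure a comparison directly, the authors' table, and leaving out each extract. The untreated replicates as separate extracts were first planned as the model and became an alternative after the data were seen. Quality marks that the scanner software gave to spots were not used, and the identity of the targeted allele was not used here.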

Results

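Gene expression in colonic mucosa was measured on 16 two-colour arrays in C57Bl/6J wild-type (WT) mice and in mice labelled Nod2-/-. Nod2 encodes an intracellular receptor for fragments of bacterial peptidoglycan. Mice of both genotypes had been left untreated, had received an antibiotic cocktail (2 g/L streptomycin, 200 mg/L gentamicin, 125 µg/L ciprofloxacin and 1 g/L bacitracin) or had received 1 g/L metronidazole in their drinking water. The 8 RNA extracts, 4 per genotype, were compared in 8 dye-swapped pairs of arrays. Untreated WT and untreated Nod2-/- extracts existed as replicates 1 and 2, and each treated group was a single extract. Median signal per array ran from 278 to 404 intensity units in Cy5 and from 175 to 266 in Cy3, and 13385 genes were measured. Changes are log2 ratios with standard errors (SE). Those of averaged effects rest on 1 treated pair per genotype. Those of direct comparisons reflect hybridisation noise alone, because the replicate untreated pairs differed no more than repeated measurements of the same extracts.

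Nod2 itself was read first. Its probe did not differ between untreated genotypes, with a log2 ratio of 0.00 between Nod2-/- and WT, and averaged over treatments the ratio was 0.05 (SE 0.148, adjusted p = 1.00). It stood at -0.26 under antibiotics and at 0.42 under metronidazole. The position of the probe relative to the deleted part is not known, so this value checks nothing about the labels. The Nod2 signal was lower in every treated extract, by -0.99 and -1.23 in WT mice given antibiotics and metronidazole, and by -1.25 and -0.81 in Nod2-/- mice.

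The effect of the antibiotic cocktail, averaged over genotypes, asks what several drugs together do to the mucosa; bacteria were not measured. The chemokine genes Ccl4 (-2.73, SE 0.413) and Cxcl10 (-2.03, SE 0.308), which attract monocytes and T cells, and Cxcl9 (-1.65, SE 0.171) were lower in both genotypes. So was Camp (-1.72, SE 0.0853), which encodes the antimicrobial peptide cathelicidin and was detected in only 25% of channels with antibiotics. Higher were Guca2a (1.18, SE 0.0675), which encodes guanylin, the fatty acid binding protein gene Fabp2 (1.85, SE 0.154) and the anion channel gene Best2 (1.25, SE 0.0967). Limma's test called 0 genes past an adjusted p of 0.05 (smallest adjusted p = 0.166), with 3114 genes at an unadjusted p under 0.05. By size, 125 genes were at least 2-fold higher and 190 at least 2-fold lower. With the untreated replicates as separate extracts limma called 26 genes (19 higher, 7 lower), and with the dye-swapped arrays counted as replicates it called 5106. It called 1281 in the single-channel model, 1263 from the direct ratios alone and 695 without either the WT or the Nod2-/- metronidazole extract.

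None of the genes named for antibiotics passed the test on its own. Higher in both genotypes, at an adjusted p of 0.166, were also Bcas1 (1.03), Upb1 (1.03), Capn9 (0.86), Hepacam2 (1.09), Anxa13 (1.28), Paqr5 (0.78) and Hgfac (0.83). Lower were the cystine transporter gene Slc7a11 (-1.61), the NF-kappaB regulators Nfkbiz (-1.37) and Zc3h12a (-1.04) and the interferon-inducible GTPase gene Gbp5 (-1.34). So were the killer cell lectin-like receptor gene Klra2 (-1.04), Uox (-1.55), Exoc3l4 (-1.38), the osteoclast cytokine gene Tnfsf11 (-0.96) and Nsg1 (-0.69). Of these, Slc7a11, Klra2 and Tnfsf11 were detected in only 37.5%, 12.5% and 25% of channels with antibiotics.

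With antibiotics 21 of the 27 lists passed limma's camera test (9 higher, 12 lower), and 0 of these passed with an estimated correlation (adjusted p = 0.658 or, where given, 0.665) or with fry (smallest adjusted p = 0.0762). All 21 cytokine and chemokine genes were lower, by a mean of -1.08 (adjusted p = 1.6e-09; adjusted p = 0.658 with an estimated correlation), and 14 passed when adjusted over the list alone. The interferon response list (25 genes) had a mean of -0.64 (adjusted p = 5.2e-09), with 17 lower when adjusted over the list alone (adjusted p = 0.658 with an estimated correlation). It was led by Gbp3 (-1.32), Oas2 (-1.13), Iigp1 (-0.96) and Tgtp1 (-0.95). All 21 neutrophil and macrophage genes were lower (mean -0.70, adjusted p = 5.97e-07), 4 of them past the test when adjusted over the list alone (adjusted p = 0.658 with an estimated correlation). Among them were the collagenase gene Mmp8 (-1.84), Cxcr2 (-1.64), Il1r2 (-1.10) and Mmp9 (-0.94). Antimicrobial and acute phase genes had a mean of -0.53 (adjusted p = 0.000607), with 3 lower when adjusted over the list alone (adjusted p = 0.658 with an estimated correlation). Ido1 stood at -1.79, Camp at -1.72, S100a8 at -1.17 and Reg3b at -1.16. NOD and Toll-like receptor signalling genes had a mean of -0.21 (adjusted p = 0.0035), with Nod2 (-1.12), Tlr2 (-0.99) and Nfkbia (-0.51) lower and Il18 higher (1.07). In that list 1 gene was higher and 6 were lower when adjusted over the list alone (adjusted p = 0.658 with an estimated correlation).

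Lymphocyte markers were lower with antibiotics as groups. The B cell list (16 genes) had a mean of -0.81 (adjusted p = 0.00145), including the coactivator gene Pou2af1 (-1.57), Ms4a1 (-1.56) and Tnfrsf13c (-1.51). The T cell list (15 genes) had one of -0.61 (adjusted p = 0.00151), including Icos (-1.18), Cd6 (-1.12), Ccl5 (-0.97) and Gzmb (-0.86). The MHC class II list (9 genes) had one of -0.51 (adjusted p = 0.00318), including H2-Oa (-0.84) and H2-DMb1 (-0.76). In these lists 0 genes passed when adjusted over the list alone, and the lists did not pass with an estimated correlation (adjusted p = 0.658 for each). Proliferation genes had a mean of -0.29 (adjusted p = 7.58e-08), with 1 lower when adjusted over the list alone (adjusted p = 0.658 with an estimated correlation). Cenpa stood at -0.66, Rrm2 at -0.58 and Mcm4 at -0.58. Endoplasmic reticulum stress genes had a mean of -0.26 (adjusted p = 6.23e-05), with the chaperone gene Hyou1 at -0.57, Manf at -0.56 and 4 genes lower when adjusted over the list alone (adjusted p = 0.658 with an estimated correlation). The matrix list, with Mmp3 at -1.75 (SE 0.793) and Timp1 at -1.27, had a mean of -0.41 (adjusted p = 0.0035). Its direct ratios lay mostly in Nod2-/- mice, with a mean of -0.70 there and -0.13 in WT mice. The immediate early list, with Egr2 at -0.79 and Ier3 at -0.76, had one of -0.21 (adjusted p = 0.0145). In both lists 0 genes passed when adjusted over the list alone (adjusted p = 0.665 for each with an estimated correlation).

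Absorptive, goblet cell, xenobiotic and fatty acid oxidation lists were higher with antibiotics. Absorptive colonocyte genes had a mean of 0.72 (adjusted p = 4.88e-07), and 14 of 19 passed when adjusted over the list alone (adjusted p = 0.658 with an estimated correlation). Sult1a1 stood at 1.55, the sodium channel gene Scnn1g at 1.40 and the anion exchanger genes Slc26a2 and Slc26a3 at 1.35 and 1.29. Goblet cell genes had a mean of 0.38 (adjusted p = 2.43e-06), and 10 of 14 passed when adjusted over the list alone (adjusted p = 0.658 with an estimated correlation). They were led by Bcas1 and the secretory lineage factor gene Atoh1 (0.69), with Retnlb at -0.57 as the exception. Xenobiotic and bile acid genes had a mean of 0.63 (adjusted p = 6.21e-06), and 12 passed when adjusted over the list alone (adjusted p = 0.658 with an estimated correlation). Among the cytochrome P450 genes Cyp2c65 stood at 2.19 (SE 0.450), Cyp2d26 at 1.62 and Cyp3a13 at 1.30. Fatty acid oxidation genes had a mean of 0.38 (adjusted p = 1.12e-05), with Ppargc1a at 0.88 and Acads at 0.80 but Angptl4 at -0.81, and 11 passed when adjusted over the list alone (adjusted p = 0.658 with an estimated correlation). The smooth muscle and adipocyte lists were higher as well. The smooth muscle list had a mean of 0.28 (adjusted p = 0.000151). Its member Ckm, a muscle creatine kinase gene that is not specific to smooth muscle, stood at 0.69. The adipocyte list had a mean of 0.57 (adjusted p = 0.00374), where Car3 stood at 1.33. Of these, 0 smooth muscle genes and 1 adipocyte gene passed when adjusted over the list alone (adjusted p = 0.658 for both lists with an estimated correlation).

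**Figure D1:**
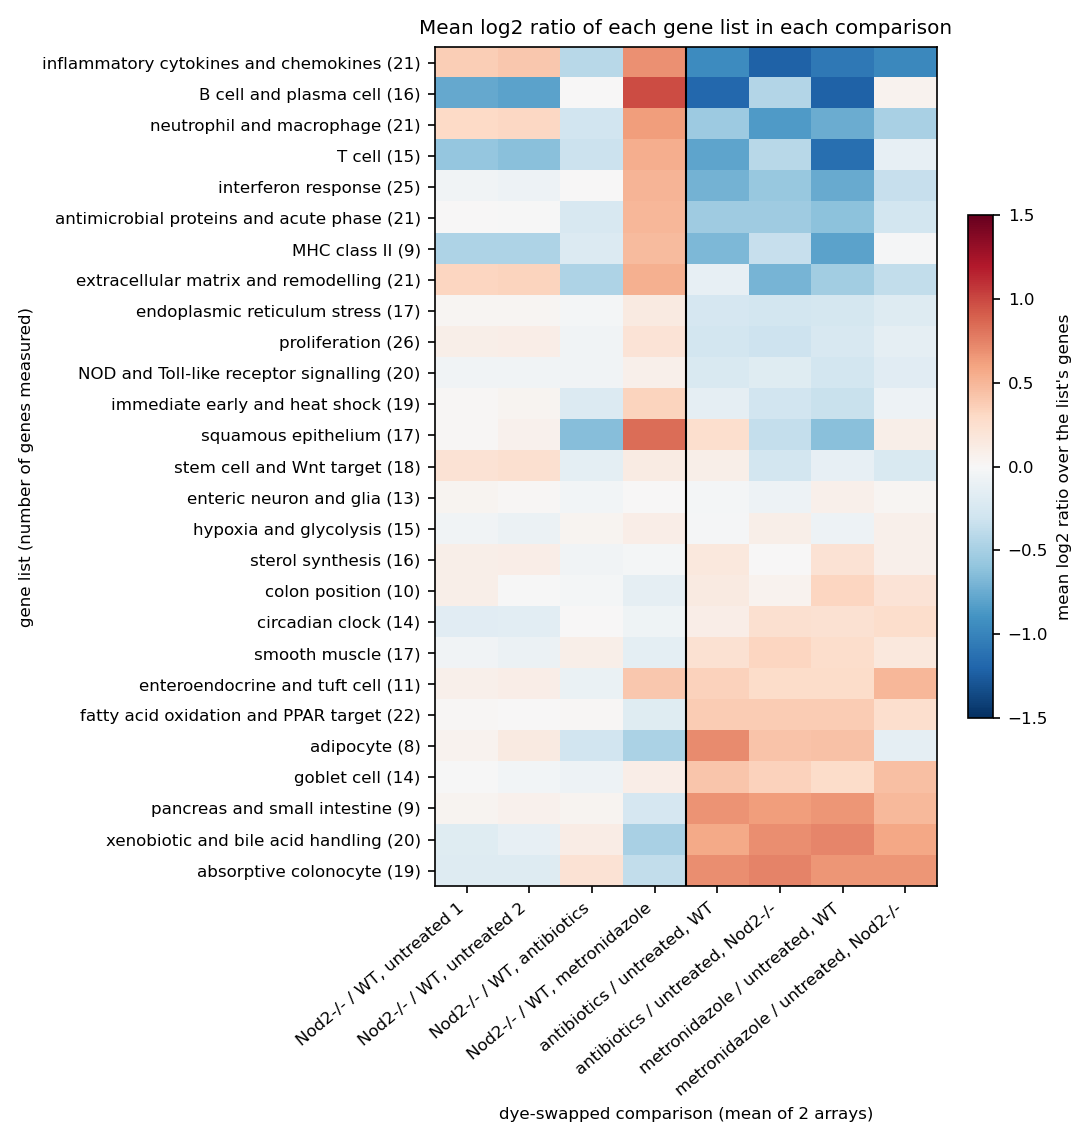
Mean log2 ratio of each gene list (number of genes in brackets) in the 8 dye-swapped comparisons, with the colour scale in log2 units. Cytokine genes were lower in all 4 comparisons of treated with untreated extracts, and the squamous epithelium list had means of -0.64 and 0.83 in the genotype comparisons under antibiotics and metronidazole.

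Metronidazole, a drug against anaerobic bacteria, was given alone to ask what it does to the same tissue. Lower were Ccl4 at -2.94 (SE 0.413), Camp at -1.72 (SE 0.0853), the urate oxidase gene Uox at -1.58 (SE 0.124) and Cxcl9 at -1.60 (SE 0.171). Fabp2 at 1.74 (SE 0.154), Best2 at 1.43 (SE 0.0967) and Guca2a at 1.20 (SE 0.0675) were higher. Limma called 0 genes (smallest adjusted p = 0.229), with 2449 at an unadjusted p under 0.05. By size, 84 genes were at least 2-fold higher and 135 at least 2-fold lower. With the untreated replicates as separate extracts limma called 2 genes (1 higher, 1 lower), and with the dye-swapped arrays as replicates 4198. The other genes named, all short of the test at an adjusted p of 0.229, were higher for Anxa13 (1.24), Upb1 (0.98), Bcas1 (0.87), the myelin protein gene Pmp22 (0.86), Paqr5 (0.83), Capn9 (0.78) and Ddn (0.75). They were lower for Slc7a11 (-1.29), Exoc3l4 (-1.17), Gbp5 (-1.13), Il1f9 (-0.81, detected in 50% of channels with metronidazole), Klra2 (-0.74), Gbp7 (-0.67) and the heme-responsive repressor gene Bach1 (-0.60). Camp, Slc7a11 and Klra2 were detected in only 37.5%, 25% and 12.5% of channels with metronidazole. The effects of the cocktail and of metronidazole share the untreated extracts, so their likeness is given only across genotypes, where no extract is shared.

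With metronidazole 22 lists passed camera (10 higher, 12 lower), and 0 passed with an estimated correlation or with fry (smallest adjusted p = 0.0762). Cytokine genes (mean -1.02, adjusted p = 1.12e-09, 14 lower when adjusted over the list alone), interferon response genes (-0.55, adjusted p = 1.41e-08, 12 lower) and neutrophil and macrophage genes (-0.62, adjusted p = 1.21e-06, 4 lower) were lower (adjusted p = 0.658 for each with an estimated correlation). In them Cxcl3 stood at -1.92, Cxcl10 at -1.91, Gbp3 at -1.17, Tgtp1 at -1.05, Mmp8 at -1.80 and the lipopolysaccharide co-receptor gene Cd14 at -0.97. T cell genes had a mean of -0.63 (adjusted p = 0.000257), with Cd6 at -1.11 and Cd8b1 at -1.08, and B cell genes one of -0.58 (adjusted p = 0.00503), with Pou2af1 at -1.22. MHC class II genes had one of -0.41 (adjusted p = 0.00814), with the master regulator gene Ciita at -0.70, and matrix genes one of -0.45 (adjusted p = 0.00039), with Mmp3 at -1.48. The direct ratios of the first 3 of these lists lay mostly in WT mice, with -1.13 in WT and -0.12 in Nod2-/- mice for T cell, -1.21 and 0.05 for B cell and -0.81 and -0.01 for MHC class II genes. Of these 4 lists, 0 members passed when adjusted over the list alone (adjusted p = 0.658 for each with an estimated correlation). NOD and Toll-like receptor genes (mean -0.22, adjusted p = 0.000349; 1 higher and 6 lower when adjusted over the list alone) and antimicrobial genes (-0.44, adjusted p = 0.00149; 3 lower), among them Ido1 at -1.83, were lower too (adjusted p = 0.658 for each with an estimated correlation). Proliferation (-0.19, adjusted p = 4.03e-05) and endoplasmic reticulum stress genes (-0.22, adjusted p = 4.19e-05) were lower with 0 members past the test when adjusted over the list alone (adjusted p = 0.658 for each with an estimated correlation). So were immediate early genes (-0.20, adjusted p = 0.0113; adjusted p = 0.665 with an estimated correlation).

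The absorptive colonocyte list was higher under metronidazole by a mean of 0.66 (adjusted p = 1.42e-07, 14 higher when adjusted over the list alone; adjusted p = 0.658 with an estimated correlation). Slc26a3 stood at 1.36 and Sult1a1 at 1.33. So were the xenobiotic list (0.66, adjusted p = 2.31e-07, 10 higher when adjusted over the list alone), the goblet cell list (0.36, adjusted p = 7.61e-07, 10 higher) and the fatty acid oxidation list (0.32, adjusted p = 1.56e-05, 6 higher), all at an adjusted p = 0.658 with an estimated correlation. In them Cyp2c65 stood at 2.17 (SE 0.450), the mucus regulator gene Clca1 at 0.58 and Angptl4, a lipase inhibitor gene, at -1.19 (SE 0.456). Sterol synthesis genes had a mean of 0.15 (adjusted p = 0.0193), with Stard4 at 0.52 and Dhcr7 at 0.48, and smooth muscle genes one of 0.21 (adjusted p = 0.000617), with 0 members past the test when adjusted over the list alone (adjusted p = 0.658 for both with an estimated correlation). Sterol genes with antibiotics (mean 0.08, median -0.00, adjusted p = 0.654) and adipocyte genes with metronidazole (0.15, adjusted p = 0.382) did not pass. Squamous epithelium (-0.05 and -0.27), stem cell and Wnt target (-0.10 and -0.17), enteric neuron and glia (-0.05, with a median of 0.02, and 0.06) and hypoxia genes (0.03, with a median of -0.01, and -0.00) passed with neither treatment (adjusted p = 0.615 and 0.0896, 0.751 and 0.257, 0.475 and 0.406, 0.966 and 0.562 in that order).

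Nod2 deficiency averaged over treatments asks what the genotype does regardless of the drugs. Among the genes named for it, Wfdc12 (0.85, SE 0.0870), a protease inhibitor gene, and Ido1 (0.84, SE 0.175), which encodes a tryptophan-degrading enzyme, were higher. Cox6a2 (-0.63, SE 0.0524) and Ttc3 (-0.45, SE 0.0539) were lower. Limma called 0 genes (every adjusted p = 1.00), with 312 at an unadjusted p under 0.05, and with the dye-swapped arrays as replicates it called 336. Only 2 genes were at least 2-fold higher and 4 at least 2-fold lower. Also named, and not past the test, were Cldn22 (0.47, detected in 37.5% of WT channels), Hsph1 (0.41), Arl14 (0.36), Fam220a (0.35), Nsg1 (0.31), Ciapin1 (0.25), Cd59a (0.24) and Cckar (0.23) as higher. The chemokine gene Cx3cl1 (-0.48), Tnfrsf19 (-0.42), Zc3h6 (-0.37), the cyclic GMP pathway genes Prkg1 (-0.34) and Gucy1a1 (-0.33), Ube2e3 (-0.28), Cobll1 (-0.27) and Cnep1r1 (-0.27) were lower without passing.

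For the averaged genotype effect 10 of the 27 lists passed camera (5 higher, 5 lower), 0 with an estimated correlation or with fry (smallest adjusted p = 0.430). When either metronidazole extract was left out 4 passed (0 higher, 4 lower) and none of the 10 was among them, so these calls were lost without the metronidazole pair. The circadian clock list, 1 of the 10, lost its call but did not owe its mean to that pair. Its direct ratios had means of -0.17 and -0.16 in the untreated pairs, 0.004 under antibiotics and -0.07 under metronidazole. When either antibiotics extract was left out 16 passed (11 higher, 5 lower). All 21 neutrophil and macrophage genes were higher on average over the treatments (mean 0.22, but -0.28 in the antibiotics pair and 0.62 in the metronidazole pair; adjusted p = 5.13e-05; adjusted p = 0.658 with an estimated correlation). Cytokine genes (0.22, adjusted p = 0.000537), interferon response genes (0.15, adjusted p = 9.66e-05) and proliferation genes (0.08, but -0.05 in the antibiotics pair; adjusted p = 4.15e-05) were higher too (adjusted p = 0.658 for each with an estimated correlation). Ccl4 stood at 1.06 (SE 0.337), Mmp8 at 0.67 and Iigp1 at 0.42. The means of the cytokine and interferon lists without either metronidazole extract were -0.01 and -0.03. Lower were xenobiotic (-0.17, adjusted p = 0.000318), absorptive colonocyte (-0.11, adjusted p = 0.00239), fatty acid oxidation (-0.05, adjusted p = 0.0134) and adipocyte genes (-0.22, adjusted p = 0.00744; adjusted p = 0.658 for each with an estimated correlation). Cyp2c65 stood at -0.53, the water channel gene Aqp8 at -0.42 and Car3 at -0.69. Without either metronidazole extract the means of the absorptive and fatty acid lists were both 0.01. In the 27 lists only Tnfrsf19 passed when adjusted over the list alone. The remaining lists did not pass, among them B cell (0.07, adjusted p = 0.511), T cell (-0.13, adjusted p = 0.237), MHC class II (-0.07, adjusted p = 0.382), matrix (0.13, adjusted p = 0.0833) and antimicrobial genes (0.08, adjusted p = 0.183). The NOD and Toll-like receptor list (mean -0.01, median 0.01), the goblet cell list (0.00 and -0.03) and the enteric neuron list (-0.00 and 0.02) had means and medians of different sign.

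Untreated Nod2-/- and WT mice were compared in 2 replicate pairs, the only comparison measured more than once. Prok2 (2.03, SE 0.0430) and Ccl4 (2.02, SE 0.197), which encode signals to myeloid cells, and the eosinophil chemokine gene Ccl24 (1.84, SE 0.0304) were higher in the Nod2-/- extracts. For Ccl4 the fitted value differed from its direct ratios of 2.34 and 2.41. The crypt genes Olfm4 (1.44, SE 0.0328) and Lgr5 (1.25, SE 0.0407), both markers of intestinal stem cells, and the mucin gene Muc5b (1.49, SE 0.0365) were higher as well. Lower were the T cell coreceptor gene Cd8b1 (-1.77, SE 0.0326) and the B cell survival receptor gene Tnfrsf13c (-1.68, SE 0.0318). So were the tight junction gene Cldn8 (-1.73, SE 0.0552), the antimicrobial lectin gene Reg3b (-1.52, SE 0.0563) and the calcium channel gene Trpv6 (-1.42, SE 0.0310). Limma called 3656 genes (1680 higher, 1976 lower; smallest adjusted p = 0.00245), and 2126 higher and 1627 lower with median centring. In the single-channel model it called 0 (smallest adjusted p = 0.0829), with 2220 at an unadjusted p under 0.05, and it called 1569 from the authors' table. At least 2-fold changes past the test numbered 23 higher and 32 lower. The other named genes past the test were Sprr2f (1.58), Cstdc4 (1.40), Mmp13 (1.37), Padi3 (1.27) and Mmp8 (1.26) as higher, and Cyp2a5 (-1.65), Adgrf1 (-1.58), P2ry10 (-1.36), Sval1 (-1.34) and Ces2e (-1.33) as lower. The pairs correlated at r = 0.855 across genes, which are not independent replicates, and 50 genes were at least 2-fold changed in the same direction in both and 0 in opposite directions. Before averaging, the dye-swapped arrays within each pair correlated at only r = 0.0015 and 0.0765. The gene-specific dye effect (SD 0.211 and 0.202) was about as large as the averaged ratios (SD 0.212 and 0.218). The ratios therefore rely on averaging to cancel it. These p-values compare the extracts, since the replicates differed no more than hybridisations do.

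Lymphocyte markers were the gene groups lowest in untreated Nod2-/- extracts. Of the B cell list 14 genes were lower past the test and 0 higher (mean -0.73, adjusted p = 2.64e-08; 15 lower and 1 higher when adjusted over the list alone; adjusted p = 0.658 with an estimated correlation). They included Fcmr (-1.31), Fcrla (-1.29) and Pou2af1 (-1.17). Of the T cell list 14 were lower and 0 higher (mean -0.61, adjusted p = 7.58e-08; 14 lower and 1 higher when adjusted over the list alone; adjusted p = 0.658 with an estimated correlation). They included Cd6 (-1.26), Cd5 (-1.13) and Icos (-0.75). All 9 MHC class II genes were lower past the test (mean -0.45, adjusted p = 3.29e-06; 9 when adjusted over the list alone), with H2-Oa at -0.97 (adjusted p = 0.658 with an estimated correlation). Absorptive genes (1 higher, 11 lower; mean -0.18, adjusted p = 0.00149; 1 and 12 when adjusted over the list alone) were lower, with Aqp8 at -0.83 (adjusted p = 0.658 with an estimated correlation). Xenobiotic genes (1 higher, 8 lower; -0.15, adjusted p = 0.00826; 1 and 8 when adjusted over the list alone) were lower too (adjusted p = 0.658 with an estimated correlation). Sult1b1 stood at -0.81 and the bile acid transporter gene Slc10a2 at -0.71.

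Myeloid, matrix and crypt genes were higher in the untreated Nod2-/- extracts. The cytokine list had 13 genes higher and 2 lower past the test (mean 0.36, adjusted p = 0.00204; 13 and 3 when adjusted over the list alone; adjusted p = 0.658 with an estimated correlation). Ptgs2 stood at 1.26, Cxcl2 at 0.92 and Il6 at 0.79. The neutrophil and macrophage list had 13 higher and 0 lower (0.28, adjusted p = 0.000143; 14 and 1 when adjusted over the list alone), with the scavenger receptor gene Cd163 at 0.79 (adjusted p = 0.658 with an estimated correlation). The matrix list had 13 higher and 1 lower (0.31, adjusted p = 6.2e-05; 13 and 1 when adjusted over the list alone), with the metalloproteinase gene Mmp10 at 0.89 and the inhibitor gene Timp1 at 0.81 (adjusted p = 0.658 with an estimated correlation). Stem cell and Wnt target genes had 13 higher and 2 lower (0.23, adjusted p = 0.000152; 14 and 2 when adjusted over the list alone), with Slc12a2 at 0.48, Axin2 at 0.41 and Tnfrsf19 at -0.52 (adjusted p = 0.658 with an estimated correlation). Sterol synthesis (4 higher, mean 0.10, adjusted p = 0.0046; 6 when adjusted over the list alone) and proliferation genes (4 higher, 0.09, adjusted p = 0.000696; 2 when adjusted over the list alone) were slightly higher (adjusted p = 0.658 for both with an estimated correlation). In all, 12 lists passed camera (6 higher, 6 lower) and 0 with an estimated correlation. With fry 3 passed, namely fatty acid oxidation (adjusted p = 0.0422), circadian clock (adjusted p = 0.0499) and endoplasmic reticulum stress genes (adjusted p = 0.0499). Antimicrobial genes went both ways (6 higher, 7 lower; mean -0.01, median 0.09, adjusted p = 0.541), with Ang4 at 0.74 and Itln1 at 0.66 against Reg3b, and so did interferon response genes (4 higher, 9 lower; -0.06, adjusted p = 0.157). Fatty acid oxidation (mean 0.00, median -0.02) and immediate early genes (0.03 and -0.02) did not pass camera and had means and medians of different sign.

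**Figure D2:**
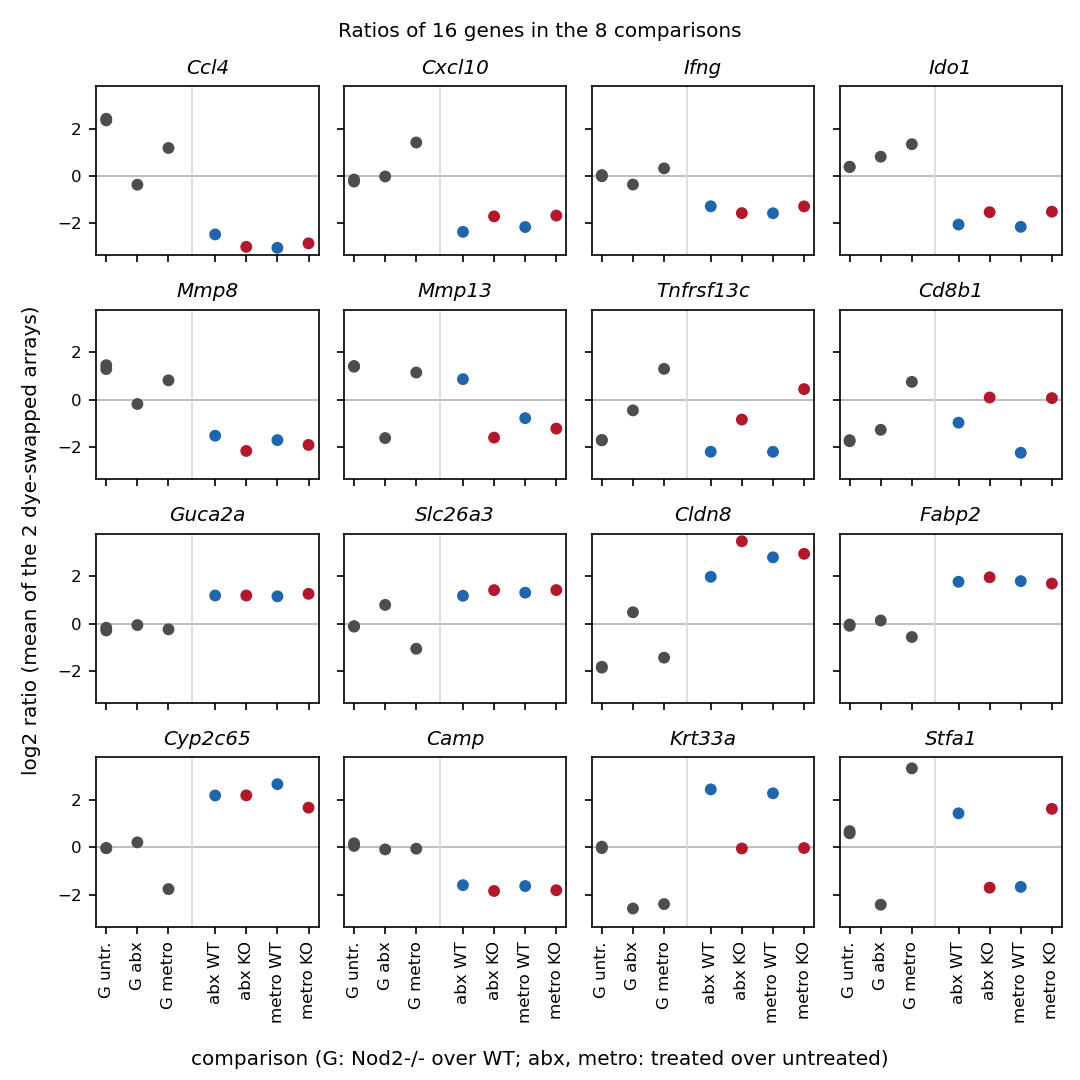
Log2 ratios of 16 genes in the 8 comparisons; each point is the mean of 2 dye-swapped arrays (grey, Nod2-/- over WT; blue and red, treated over untreated in WT and Nod2-/- mice). Ccl4 and Cxcl10 lie below 0 in all 4 treatment comparisons and Cldn8 in both untreated genotype pairs, while Stfa1 has genotype ratios of -2.42 and 3.33 under antibiotics and metronidazole.

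Under antibiotics the genotypes were compared in a single pair of extracts, to ask whether the genotype difference persists under these drugs. Hair and skin genes were far lower in the Nod2-/- extract, with the hair keratin genes Krt33a at -2.56 and Krt71 at -2.26, the hair follicle gene Tchh at -2.51, Krtap19-9b at -2.38 and the protease inhibitor gene Stfa1 at -2.49. Higher were Clec2d (1.16), the immunoglobulin joining chain gene Jchain (1.02), the mitochondrial transhydrogenase gene Nnt (1.00), an immunoglobulin kappa variable gene (0.98) and Sh3d19 (0.96). Limma called 1491 genes (346 higher, 1145 lower; smallest adjusted p = 0.00273), 3 of them at least 2-fold higher and 129 at least 2-fold lower. The split was 1001 and 1923 with an intensity trend, 1056 and 1989 with 16 arrays as observations, 1 and 21 in the single-channel model and 37 and 280 from the authors' table. Of the squamous epithelium list 14 of 17 genes were lower and 0 higher (mean -0.62), with Trp63 at -1.25, Krt4 at -1.24 and Krtdap at -1.23. The matrix list had 11 lower and 0 higher (mean -0.40), with Mmp13 at -1.46, and the neutrophil and macrophage list 9 lower and 0 higher (mean -0.21). The medians of these 3 lists lay below every one of 10000 random lists, that is, at percentile 0. Random lists hold genes drawn independently, while genes of these lists vary together. Such a place therefore describes this pair of extracts and is no test of the genotype. B cell genes went both ways (5 higher, 5 lower; mean 0.03), with Ms4a1 at -0.83.

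Under metronidazole the same question was asked in another single pair. Many differences ran the other way, but the hair genes Krt33a and Krt71 and the adipocyte list were lower under both drugs. The Nod2-/- extract had higher levels of Stfa1 (3.49) and Stfa2 (2.87, detected in 25% of WT channels), of the cornified envelope genes Lce3f (2.76) and Sprr2f (2.74) and of the cytochrome P450 gene Cyp2a5 (2.95). Krt33a (-2.37), Krt71 (-1.98), the carbonic anhydrase gene Car3 (-1.80), the muscle calcium pump regulator gene Sln (-1.64) and the nuclear receptor gene Nr5a2 (-1.56) were lower. Limma called 4367 genes (2641 higher, 1726 lower; smallest adjusted p = 0.00151), and 1967 higher and 2994 lower with median centring or 72 and 3 in the single-channel model. At least 2-fold changes past the test numbered 232 higher and 34 lower. Members of the squamous (16 higher, 0 lower; mean 0.80), neutrophil and macrophage (20 and 0; 0.59), interferon response (20 and 0; 0.47) and MHC class II lists (8 and 0; 0.43) were higher. So were B cell (12 and 0; 0.85), T cell (11 and 0; 0.51) and cytokine genes (15 and 1; 0.60). Pou2af1 stood at 2.02, Mmp3 at 1.87, Krtdap at 1.66, Trp63 at 1.60, Ccl4 at 1.39 (1.18 as a direct ratio) and Gbp3 at 1.10. Xenobiotic genes were lower (1 higher, 11 lower; mean -0.43), with Cyp2c65 at -1.55 and the retinal dehydrogenase gene Aldh1a1 at -0.96, as were adipocyte genes (0 higher, 5 lower; mean -0.49). Medians of the squamous, B cell and neutrophil and macrophage lists lay above all 10000 random lists, at percentile 100. As under antibiotics, such a place describes the pair of extracts and is no test of the genotype.

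**Figure D3:**
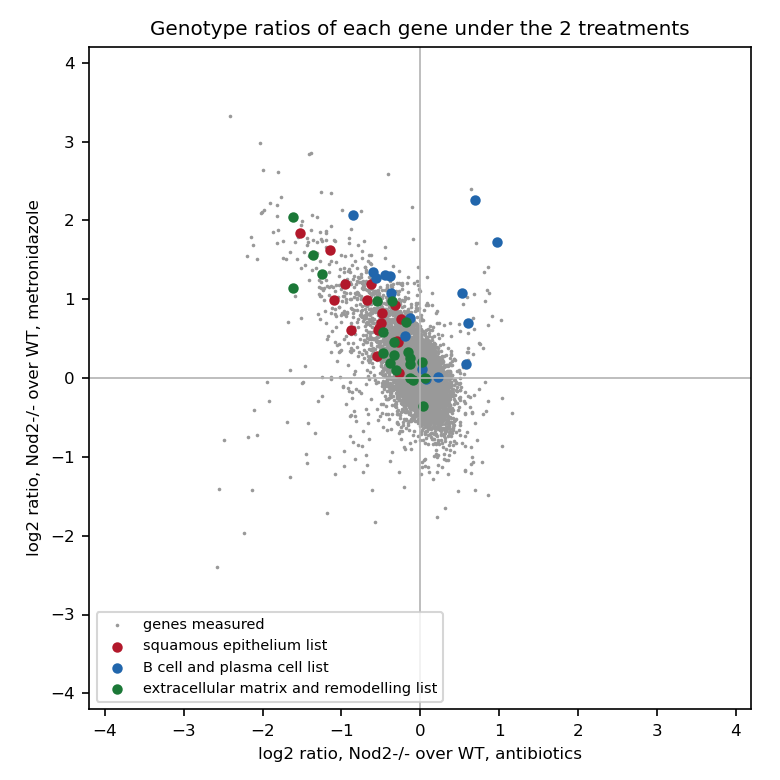
Log2 ratio of Nod2-/- over WT for each of 13385 genes under antibiotics (x axis) and metronidazole (y axis), with squamous epithelium (red), B cell (blue) and matrix genes (green) marked. The ratios correlate at r = -0.544 across genes, and 95 genes are at least 2-fold changed in opposite directions against 9 in the same one.

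The genotype ratios under antibiotics and metronidazole had a correlation of -0.544 across genes, and genes are not independent replicates. The untreated genotype ratios correlated with neither, with r = -0.0424 and -0.0570 against antibiotics and 0.0446 and 0.0495 against metronidazole. Whether the response to a drug differed between genotypes was tested as an interaction, which again compares single extracts. For antibiotics limma called 2656 genes (1070 higher, 1586 lower in the Nod2-/- response; smallest adjusted p = 0.00379). The higher response was led by Cldn8 (2.00), the immunoglobulin genes Igkv4-55 (1.92) and Igkv4-59 (1.87), Pou2af1 (1.81) and the sialyltransferase gene St8sia5 (1.66), against Krt33b at -3.12, Stfa1 at -3.08, Stfa2 at -3.04, Mmp13 at -2.83 and Stfa3 at -2.54. In the single-channel model limma called 0, with 1499 genes at an unadjusted p under 0.05. For metronidazole it called 3256 (2112 higher, 1144 lower; smallest adjusted p = 0.00174), or 1580 and 2512 with median centring and 55 and 1 in the single-channel model. Cyp2a5 (4.60), Cyp2a4 (3.60), Lce3f (3.58), Khdc1a (3.36) and Pou2af1 (3.19) had the higher response, and Krt33b (-2.40), Krt33a (-2.35), Prok2 (-2.14), Car3 (-2.06) and Krt71 (-1.97) the lower one.

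In WT mice each drug was compared with water in 1 pair of extracts. Antibiotics left lower levels of Pou2af1 (-2.47), Cxcl10 (-2.18), Tnfrsf13c (-2.15), Khdc1a (-2.15) and the leukocyte phosphatase gene Ptprc (-2.09). Higher were the skin genes Kprp (2.68) and Lce3f (2.58), the hair genes Krtap19-9b (2.62; like Kprp, detected in 33.3% of untreated WT channels) and Krt33a (2.46) and the transcription factor gene Foxa2 (2.30). Metronidazole left lower Ptprc (-3.11), Ifi202b (-2.87), Pou2af1 (-2.82), Ccdc88b (-2.70) and Elf5 (-2.67, detected in 25% of channels with the drug). Higher were Cyp2c65 (2.90), Cldn8 (2.73), Foxa2 (2.66), the arylacetamide deacetylase gene Aadac (2.51) and Hao2 (2.48). Limma called 5441 genes for antibiotics (2784 higher, 2657 lower; 3804 and 2097 with median centring) and 6824 for metronidazole (3208 higher, 3616 lower; 4925 and 2655 with median centring), and 2362 and 4072 in the single-channel model. At least 2-fold changes past the test numbered 158 higher and 164 lower for antibiotics and 166 and 468 for metronidazole. B cell genes were lower with antibiotics (0 higher, 15 lower; mean -1.19) and with metronidazole (0 and 15; -1.37), and so were T cell genes (1 and 14, -0.77; 0 and 14, -1.18) and interferon response genes (0 and 22; 0 and 23, -0.81). Xenobiotic genes were higher with both (16 and 1, 0.53; 17 and 1, 0.80).

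In Nod2-/- mice the drugs were again compared with water in single pairs. Cldn8 (3.72 with antibiotics, 3.00 with metronidazole) and Sval1 (3.13 and 2.88) stood highest, followed by the sulfotransferase gene Sult1d1, Hao2 and Aadac (2.80 to 2.46) with antibiotics. With metronidazole Lce3f, Kprp and Cyp2a5 (2.62 to 2.39) followed. Ccl4 (-3.68 and -3.25) and Wfdc21 (-2.52 and -1.91) were among the lowest with both, as was Cstdc4 (-2.09 with metronidazole). Ifi202b (-2.93) and Cxcl3 (-2.52) joined them for antibiotics, and Prok2 (-2.37) and Mmp8 (-2.02) for metronidazole. These are fitted values, and the ratios measured directly in these pairs were smaller for several genes. Ccl4 stood at -2.99 with antibiotics and -2.84 with metronidazole in them, so its ratios did not close around the loops. With antibiotics the direct ratios of Wfdc21, Ifi202b and Cxcl3 were -2.15, -2.62 and -2.03. Limma called 7154 genes for antibiotics (3434 higher, 3720 lower) and 4213 for metronidazole (2294 higher, 1919 lower). In the single-channel model it called 4688 and 289, and the authors' table gave 2271 for metronidazole. At least 2-fold changes past the test numbered 181 and 370 for antibiotics and 103 and 48 for metronidazole. Cytokine genes were lower in both (0 higher, 21 lower, mean -1.39; 0 and 20, -0.90), and absorptive colonocyte genes higher (15 and 1, 0.87; 16 and 1, 0.60). B cell genes were lower with antibiotics (1 higher, 10 lower; -0.43). With metronidazole 6 were higher and 0 lower in the fit (0.21). The direct ratio had a mean of 0.05 (SE over the list's genes 0.0475), so no change of this list is claimed there.

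Across genotypes, where no extract is shared, the response to antibiotics in WT mice correlated with that in Nod2-/- mice at r = 0.702 across genes. At least 2-fold changes had the same direction for 175 genes and opposite ones for 4. For metronidazole the value was r = 0.587 (87 and 7 genes). The response to metronidazole in WT mice was closest to that to antibiotics in Nod2-/- mice (r = 0.829; 321 and 0 genes), and antibiotics in WT against metronidazole in Nod2-/- mice gave r = 0.580 (99 and 2 genes). Genes are not independent replicates, and each response rests on 1 pair of extracts. Along the first principal component of the fitted levels, with 68.4% of the variance, untreated WT and Nod2-/- extracts lay at -23.6 and -26.2, Nod2-/- with metronidazole at -5.13, WT with antibiotics at 8.23, Nod2-/- with antibiotics at 21.4 and WT with metronidazole at 25.3.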

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

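The tests of a turned ratio, of exchanged extracts and of the share of epithelium were chosen only after the opposing genotype differences had been seen, and that of the epidermis genes after their values had been seen, while the tests of the hair genes themselves and the count over genotype assignments were fixed before their results were seen, that of skin for both treated WT extracts together, and it was split by extract only afterwards.

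Drug responses that differed between genotypes were picked out by a test of the difference itself, the genotype by treatment interaction in limma, and list means by their place among random lists. With antibiotics 2656 genes differed in response between the single extracts, and the Nod2-/- response was lower by a mean log2 of -0.62 for cytokine genes, -0.71 for matrix genes and -0.66 for squamous epithelium genes, and higher by 0.76 for B cell genes. With metronidazole 3256 genes differed. There the Nod2-/- response was higher by 1.58 for B cell genes, 1.11 for T cell genes, 0.88 for MHC class II genes, 0.76 for squamous epithelium genes and 0.53 for interferon response genes, and lower by -0.58 for adipocyte genes. The spread behind these tests is that of hybridisation, so they show that the extracts differed and not that the genotypes respond differently.

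Genotype differences under antibiotics and metronidazole opposed each other across genes. A ratio turned the wrong way is argued against, because turning the genotype pair of either drug widened the sum around its closed loop by a factor of at least 2.46. A different share of epithelium in the biopsies as the whole cause cannot be decided. Under metronidazole smooth muscle markers were lower (mean -0.15, SE over the list's genes 0.0562) while B cell markers were higher (0.98, SE over genes 0.176). The rule set for this test counts such opposite signs against that cause. However, genes of a list vary together and come from 1 pair of extracts, so these SEs do not measure the spread between biopsies. Other lists moved as that cause would have it. Absorptive colonocyte genes had means of 0.22 under antibiotics and -0.37 under metronidazole. Matrix (-0.46 and 0.54) and neutrophil and macrophage genes (-0.28 and 0.62) ran the other way. Goblet cell genes (-0.08 and 0.10) did not follow the absorptive ones. Exchanged WT and Nod2-/- extracts under metronidazole, or equally under antibiotics, cannot be told apart from correct labels with so few genes: of the 12 genes near Nod2 chosen from the other pairs, 5 had the same sign under metronidazole (exact binomial p = 0.774; 70 of 374 genes elsewhere), and in the same test of antibiotics 5 of 12 did (exact binomial p = 0.774; 114 of 698 elsewhere). An exchange in 1 treated pair would turn the correlation of -0.544 between the treated genotype ratios positive. The closest responses were those of WT to metronidazole and of Nod2-/- to antibiotics (r = 0.829). Those of both genotypes to the same drug were less alike (r = 0.702 for antibiotics and 0.587 for metronidazole). After such an exchange the treated extracts of the closest responses would share a genotype. These values bear on an exchange without deciding it. Squamous epithelium genes were among those that opposed each other, with list means of -0.64 under antibiotics and 0.83 under metronidazole. Squamous tissue in single biopsies was not tested as a source of this opposition. A difference between genotypes in their response to the drugs, or between the mice sampled, stays open and untested too, since each treated group is 1 extract.

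The named hair keratin genes were higher in the treated WT extracts, but not all hair genes were. Of 27 further hair genes, none among the named ones, 21 were higher and 6 lower than in untreated WT with antibiotics. With metronidazole these counts were 19 and 8. Krt36 (-0.72 and -0.85), Krt84 (-0.51 and -0.83) and Krt75 (-0.42 and -0.98) were among those lower with both. A fault of a single hybridisation or of a dye is argued against. The median of the 27 genes was higher in the treated WT extract on 8 of 8 arrays, with medians from 0.11 to 0.84 in both dye orientations. Hair-bearing skin in the antibiotics WT extract is a candidate source. The median of the 27 genes in Nod2-/- over WT was -0.78 there (27 of 27 lower, random lists -0.09 to 0.05). It was -0.05 and 0.04 in the untreated pairs, and 0.79 with antibiotics over untreated WT. Genes entered only if detected in every channel of at least 1 extract. Hair genes dim elsewhere could thus enter through the extract where they were high. The random lists do not share this choice, so these values are partly set in advance. In the same WT comparison 21 genes of the cornified epidermis, dim in untreated WT, had a median of 1.07. It was also 0.98 with metronidazole and 0.41 with antibiotics in Nod2-/- mice, where the hair genes stood at -0.02 and -0.02. The rise of the epidermis genes is thus not particular to hair-bearing skin. Being dim in untreated WT, they had to be detected in another extract, so a rise in some extract was built in. Skin with its epidermis in the metronidazole WT extract is argued against, although the hair genes met what had been predicted there. Those 21 genes had a median of -0.0343 over untreated WT (SE over genes 0.0527, with -0.13 to 0.13 in random lists). That of the hair genes was 0.16 there. In Nod2-/- over WT the hair genes stood at -0.11 (19 lower and 8 higher, with -0.07 to 0.10 in random lists). Hair follicles without epidermis in that extract and biological explanations were not tested, and the labels name no dissection step that would remove skin.

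For Nod2 deficiency averaged over treatments, 3 of the 4 assignments of genotype within treatments, the real one included, gave at least the 312 genes at an unadjusted p under 0.05 that the real one gave. The highest of the others gave 1359, with the antibiotics pair turned, several times the real count; that structure of the samples is the opposition of the treated genotype ratios (r = -0.544), which turning either pair removes, and no separate sign. With 4 assignments no share under 0.05 can be reached.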

How the results depend on the processing

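The fit with the untreated replicates as separate extracts was chosen as an alternative only after the data had been seen; all other alternatives were planned. Of the counts under an alternative, 193 stayed within 1.5 times the reported count and 55 did not. List means kept their side of the threshold in 1520 cases, and 50 passed newly, 40 no longer passed and 10 changed sign. Named genes kept their side, or stayed within the replicate spread where no test was possible, in 2525 cases. They moved by more than that spread in 137 and gained or lost the call in 222 and 70. A change of sign was counted only for lists and genes past the test in the main fit, and no such gene had one. Among the others, which include all genes named for the averaged effects, changes of sign were not counted. The cause was not tested where none is given.

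Counting dye-swapped arrays as replicates, with 1 dye term or 1 per slide, gave 336 or 89 genes for Nod2 deficiency averaged over treatments, 5106 or 4199 for antibiotics and 4198 or 3193 for metronidazole, where limma's reported counts were 0 (312, 3114 and 2449 at an unadjusted p under 0.05). It gave 3045 or 2929 for Nod2 deficiency under antibiotics, 4944 or 4839 for the antibiotics interaction and 5448 or 5423 for the metronidazole interaction. This setting measures hybridisation noise by construction. For antibiotics averaged over genotypes the single-channel model gave 1281 genes, the direct ratios alone 1263 and the separate untreated replicates 26, and for metronidazole the latter gave 2.

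The single-channel model gave 0 genes for Nod2 deficiency in untreated mice (2220 at an unadjusted p under 0.05), 22 under antibiotics, 75 under metronidazole, 2362 and 4072 for antibiotics and metronidazole in WT mice, 4688 and 289 in Nod2-/- mice, and 0 (1499 at an unadjusted p under 0.05) and 56 for their interactions with genotype. The authors' table gave 1569 for the untreated genotypes, 317 under antibiotics, 2876 under metronidazole, 2271 for metronidazole in Nod2-/- mice, and 621 and 1782 for the interactions. Without background correction the untreated genotypes gave 2376, the antibiotics genotypes 871 and the antibiotics interaction 1496. Without a filter on dim probes the counts were 2313, 829 and 1473, and 2729 for metronidazole in Nod2-/- mice, with more genes tested. An intensity trend with robust moderation gave 2924 for the genotypes under antibiotics and 4201 for the antibiotics interaction.

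Leaving out 1 extract moved antibiotics averaged over genotypes between 0 and 695 genes, with 695 without WT metronidazole or without Nod2-/- metronidazole, either of which removes the same residual. The other leave-outs moved no count of genes past the test by more than 1.5 times. Counts at an unadjusted p under 0.05 moved more: for Nod2 deficiency averaged over treatments from 312 to 982 without either antibiotics extract and 653 without either metronidazole extract, for antibiotics from 3114 to 1406 without Nod2-/- antibiotics, and for metronidazole from 2449 to 1468 without WT and 3775 without Nod2-/- metronidazole. Where the untreated extracts were left out of the direct comparisons no residual degrees of freedom remained, so there was no test. A lone extract is assumed to vary like the other groups. Lists past camera for Nod2 deficiency averaged over treatments ranged from 4 (without either metronidazole extract) to 16 (without either antibiotics extract), against 10, and none of the 10 was among the 4. The means of 5 of these lists changed sign without either metronidazole extract and were farthest from that without either antibiotics extract. They ran from -0.0113 to 0.540 for cytokine, from -0.0316 to 0.225 for interferon response, from -0.00347 to 0.246 for enteroendocrine and tuft cell, from -0.280 to 0.0135 for absorptive and from -0.0861 to 0.0132 for fatty acid oxidation genes. The single-channel model gave 17 such lists. With an estimated correlation 0 lists passed in each of the 4 contrasts, and with fry 0, 0 and 0 for the averaged effects and 3 for the untreated genotypes, against 10, 21, 22 and 12 with camera; fry asks a different question.

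No paired analysis was possible because the treated groups have only replicate 1, and the untreated genotypes, which share replicates 1 and 2, were measured as ratios within each pair, so that the fits of ratios already pair them. Scanner processed signals were planned as a source of values and not run, since the tables hold none, and 2 lists had too few genes. Between 47.4% and 59.4% of spots were detected per channel and array, so genes near background cannot be judged.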

Other observations

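The tests of genes near Nod2 were chosen only after their values had been seen.

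Enteroendocrine and tuft cell genes split with both treatments. The hormone genes Gcg (1.18 with antibiotics, 1.26 with metronidazole, SE 0.215 each), Chga (0.89 and 0.88) and Insl5 (0.90 and 0.86) were higher and Alox5ap (-0.79 and -0.67), a leukotriene pathway gene, was lower, for list means of 0.31 (adjusted p = 0.0317) and 0.38 (adjusted p = 0.00726). Adjusted over the list alone, 5 were higher and 1 lower with antibiotics, and 6 and 1 with metronidazole (adjusted p = 0.665 and 0.658 with an estimated correlation). The list's mean for Nod2 deficiency averaged over treatments was 0.13 (adjusted p = 0.00226; adjusted p = 0.658 with an estimated correlation), with Avil at 0.29, and it did not pass without either metronidazole extract (mean -0.00). Genes of the small intestine and pancreas were higher with both treatments, with means of 0.65 (adjusted p = 0.000749) and 0.58 (adjusted p = 0.000439), among them the lipoprotein gene Apob (1.48 and 0.89), the elastase gene Cela1 (0.95 and 1.03) and the retinol binding gene Rbp2 (0.68 and 0.59), and 4 passed in each when adjusted over the list alone (adjusted p = 0.658 for both with an estimated correlation).

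Colon position genes had a mean of 0.27 with metronidazole (adjusted p = 0.0134; adjusted p = 0.658 with an estimated correlation), with Cdx1 at 0.83 and Hoxa13 at 0.57, and 0 passed when adjusted over the list alone. With antibiotics the list did not pass (0.10, adjusted p = 0.156), with Cdx1 at 0.90 against Cdx2 at -1.39 (SE 0.186), and 4 genes were higher and 1 was lower when adjusted over the list alone. Circadian clock genes had means of 0.17 with antibiotics (adjusted p = 0.0239) and 0.25 with metronidazole (adjusted p = 0.00269), with Dbp at 0.68 and Nr1d2 at 0.56 in the latter, and 0 and 5 genes passed when adjusted over the list alone (adjusted p = 0.658 for both with an estimated correlation). Their mean was -0.08 for Nod2 deficiency averaged over treatments (camera, adjusted p = 0.0141). The list did not pass without either metronidazole extract, although the direct mean of that pair was only -0.07 (0.004 under antibiotics). In untreated mice the mean was -0.16 (camera, adjusted p = 0.0209), with Hlf at -0.52 and Dbp at -0.49. There 1 gene was higher and 4 were lower past the test, and 2 and 8 when adjusted over the list alone. Neither contrast passed with an estimated correlation (adjusted p = 0.658 for both). The labels give no time of sampling. Of the erythrocyte genes, which were too few to test, Hba-a1 stood at -0.11 with antibiotics and -0.01 with metronidazole. The sex-linked list held 1 measured gene and gives no result.

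Genes near Nod2 were examined because a targeted allele can carry flanking DNA of another strain. Of 141 genes within 10 Mb, 7 (4.96%) had an unadjusted p under 0.05 for Nod2 deficiency averaged over treatments, and 2.30% of genes on other chromosomes had one. Against all genes beyond 30 Mb, on chromosome 8 or another, the two-sided Fisher exact p was 0.0475 (odds ratio 2.21). This share lay at percentile 91.8 of 10269 equally long runs of neighbouring genes, the highest of which reached 7.09%, so flanking DNA may contribute but cannot be told apart from the clustering of genes along chromosomes. Cx3cl1 (-0.48), Cnep1r1 (-0.27), Rpgrip1l (-0.22), Rbl2 (0.31), Ciapin1 (0.25) and Neto2 (0.20) had the same sign in all 4 genotype pairs, and Best2 (-0.23) had not; each had an adjusted p of 1.00, and the 7 are named, after their values were seen, because they make up this count. A mismatch of the probe at a strain variant stays open as well, since only 3 other probes exist, with a median ratio of -0.0644 to the probe used (Cnep1r1 0.767, Neto2 -0.360, Rbl2 -0.0644).

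The mitochondrial gene Nnt, which differs between C57BL/6 substrains, had Nod2-/- over WT ratios of 0.82 and 0.56 in the untreated pairs, 1.04 under antibiotics and -0.86 under metronidazole. Treated over untreated, it stood at 0.46 with antibiotics and 1.53 with metronidazole in WT mice, and at 0.58 and 0.009 in Nod2-/- mice. Its level is thus not fixed by the strain alone. The turned sign bears on the labels of the metronidazole pair, whose exchange stays open (5 of 12 genes near Nod2 had the same sign there). A single gene that also moves with the drugs, picked out after its values were seen, decides nothing.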
